A study of Homo sapiens with 6 samples.

How the data were processed

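RNA immunoprecipitation followed by sequencing (RIP-seq) was done by the authors in Beas2B cells, untreated or given 10 µM DFO for 16 h, with 2 IRP2 libraries and 1 library of nonspecific rabbit IgG per treatment, 6 libraries in all. Per the submitters' notes, reads were processed with Bowtie2 2.0.6, TopHat2 2.0.7, SAMtools 0.1.18 and HOMER 4.4 on hg19. Per the file headers, the authors merged the 2 IRP2 libraries of each treatment, and findPeaks of HOMER took windows of 110 bases in the untreated pool and 224 bases in the DFO pool, the estimated fragment lengths. It kept windows with at least 2-fold over the compared library and at least 2-fold over the surrounding 10000 bases, with no p-value threshold and with tags of both strands together. The 4 lists set each IRP2 pool against IgG and against the other IRP2 pool. No list gives values per replicate.

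The signal values are, per the file headers, the authors' tag counts per window scaled to 10000000 tags of the pool, and the tags of the compared library, raised by the caller to a floor (1.7 and 3.2 against IgG, 3 and 6.1 between pools). In 1 list, the deposited whole tag count per window is also given. Each fold is the authors' ratio of depth-scaled tags of the peak pool to the compared library, and a further ratio sets the window against its surroundings. Each p-value is the authors' HOMER output for the pooled tags and holds no spread between replicates. The findPeaks score deposited for each window was not used. The deposited annotated tables (peaks found over IgG and over the other pool for untreated cells, the same for DFO, and peaks of both treatments) add the HOMER annotation, hits of an IRE motif supplied by the authors, and the fraction of G and C bases, which was not used. The compared library lay at the floor in 52.9%, 62.0%, 62.6% and 49.7% of the windows of untreated over IgG, DFO over IgG, untreated over DFO and DFO over untreated. Folds there are lower bounds.

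Whole tags were recomputed from the normalised values and the pool totals. They fell within 0.15 of a whole number in 100% of windows. The totals of the IgG libraries were estimated from fold, tags and compared tags. Each fold was given a 95% exact conditional (Clopper-Pearson) interval from the tags of the windows. Reads amplified by PCR are not independent molecules, so the intervals cover counting error only. The lists are unstranded, since every window is listed on the plus strand. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and gene names and transcripts of GENCODE 29.

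Genes were taken from the transcript in the annotation of each peak. The plan, fixed before the data were examined, named the gene that the tables give, and the tables give both a transcript and the gene of the nearest promoter. The transcript was chosen after the tables were seen. The nearest promoter's gene was the same in 61.7%, 61.4% and 60.3% of the peaks in transcripts of the tables of untreated only, DFO only and both treatments. Of 154 list tests, 27 passed with the transcript and 8 of these also with the nearest promoter. Annotation covered 72.0%, 70.4%, 57.9% and 80.9% of the windows of the 4 lists, in the order above, and gene lists see only these.

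The rule for named genes took, in each list, the 10 genes with the highest fold among windows at or above the median tag count, the 5 genes with the most tags, every canonical IRE mRNA, up to 10 cytochrome c oxidase genes and the 2 members of every other list with the most tags. Pseudogenes and genes with near-identical copies were to be named only as uncertain. The rule was fixed before the data were examined, and 3 genes that the rule named are not reported here. Of 23 gene lists fixed at the same time, the mitochondrial genome had no named gene in the tables, and 22 were tested in the 3 tables and 4 lists. The background was the 7300 genes with a peak in any annotated table. Membership was compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 154 tests and a threshold of 0.05, and each list was ranked among 10000 random lists matched on tag count. Genes are not replicates, so the tests describe these pooled libraries. Windows were shared when they overlapped by at least 1 base, and the number shared was set against 1000 draws matched on tag count. Shares of annotation classes have exact binomial intervals.

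On simulated data, the overlaps planted were all found. With no planted difference, the share of list tests with p under 0.05 lay between 2.80% and 4.55% (2000 draws). With planted odds of 4, it was 52.3% for 10 genes and 95.7% for 30 genes in DFO only, 52.7% and 95.7% in both treatments, and 0% and 54.3% in untreated only. A list of 10 genes therefore could not show enrichment among the peaks of untreated cells, in which 81.1% of the background had a peak.

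The alternatives fixed before the data were examined were a p-value of 1e-10 or lower, at least 8-fold, tag counts at or above the median, other overlap rules, omission of the mitochondrial genome and unplaced sequence, exon, UTR and end-of-transcript windows alone, a background at or above the median tag count, and 1 peak per gene. Those added after seeing the data were adjustment over all putative peaks, 1 tag minimum for all lists, totals without pile-ups (windows with 10000 or more normalised tags), the gene of the nearest promoter, and omission of windows that overlap a call in the opposite direction. The planned search for IRE structures in the peaks was not run, since sequence of hg19 was not used here. A stem-loop search in the UTRs of GENCODE 29 transcripts and the authors' motif took its place. The windows of the pools are counted on different fragment lengths. Of the windows higher in untreated cells, 759 (2.38%) overlapped 724 windows (9.80%) listed as higher after DFO. In 91 of these pairs the smaller window lay inside the larger, and in 56 of the 91 it held more untreated tags than the larger was credited with.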

Results

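RNA bound to iron regulatory protein 2 (IRP2) was sequenced from Beas2B cells, an immortalised human bronchial epithelial line. The question was which RNAs IRP2 holds with and without an iron chelator. IRP2 recognises iron-responsive elements (IREs), stem-loops in the untranslated regions (UTRs) of mRNAs of iron metabolism. Cells were left untreated or were given 10 µM deferoxamine (DFO), an iron chelator, for 16 h. Each treatment had 2 IRP2 libraries, pooled by the authors before peaks were called, and 1 library made with nonspecific IgG. The pools held 28742004 tags from untreated cells and 27390878 tags after DFO, and the IgG libraries 15175689 and 14436353 tags as estimated from the listed folds. Values per replicate were not used here, since the lists give pooled values, so no difference could be set against the spread between replicates. Folds are the authors' own, per window, and ranges in parentheses are 95% exact conditional intervals that cover counting error only. Where the compared library lay at the caller's floor, the fold is a lower bound and is given as "at least". Input RNA was not analysed here, so the amount of an RNA in the cell and its capture by IRP2 were not measured apart. Coordinates are on hg19.

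In untreated cells, among genes chosen by fold, the highest listed fold over IgG lay at BCYRN1, a noncoding RNA of the Alu family, with 41.7-fold (11.4–347) at chrX 70948803–70948913, in noncoding exon 1 of 4. CD68, a lysosomal membrane protein, had 22.5-fold (7.54–111) in a promoter-proximal window on chr17. The protein disulfide isomerase PDIA6 had 18.1-fold (6.03–89.3) in its 3' UTR, the redox protein TXN 16.4-fold (4.34–138) in exon 5 of 5, and BEX1 15.0-fold (3.98–127) in its 3' UTR. Folds were at least 22.8 for the glycolytic enzyme PGAM1, 19.9 for the lysosomal enzyme PPT1, 17.4 for the matrix protein EFEMP1 and 15.8 for the chromatin protein HMGB1. BCYRN1, PGAM1 and HMGB1 have near-identical copies elsewhere in the genome, so their windows are uncertain. Among windows with a named gene, those with the most tags were also uncertain. MTRNR2L2 (3.28-fold, 3.15–3.42), MTRNR2L1 (3.84-fold, 3.65–4.04), MTRNR2L10 (3.40-fold, 2.99–3.88) and MIR4485 (3.94-fold, 3.70–4.19) lie in nuclear copies of mitochondrial ribosomal RNA. The window named GSTA4 (6.82-fold, 6.21–7.52) lies at the promoter of a gene whose neighbour is the 7SK RNA. Among messenger RNAs of the fixed lists, EEF1A1, a translation elongation factor, had 1153 tags and 2.11-fold (1.85–2.40). The heat shock protein HSPA8 had 2.27-fold (1.81–2.88), the intermediate filament VIM 3.76-fold (2.71–5.35), the matrix proteins CCN1 and SPARC 4.39-fold (2.81–7.18) and 5.63-fold (3.31–10.3), and the ribosomal proteins RPS6 and RPS24 2.07-fold (1.65–2.63) and 2.18-fold (1.70–2.81). EEF1A1, HSPA8 and the ribosomal protein genes have processed pseudogenes, so their tags are uncertain here and in the comparisons that follow. In all, 30150 windows of 110 bases reached 2-fold, of which 14383 had an authors' p-value above 0.05 and 5188 passed a Benjamini-Hochberg adjustment over the 353502 putative peaks.

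After DFO, the cell cycle inhibitor CDKN1A had, over IgG, 55.9-fold (23.8–173) in its 3' UTR at chr6 36654261–36654485, the DNA damage gene GADD45A 41.6-fold (21.0–96.9) in its 3' UTR, and MDM2, the ubiquitin ligase that degrades p53, 24.3-fold (15.6–39.9) in exon 11 of 11. Folds were at least 34.7 for the antiproliferative gene BTG2, 30.5 for the stress transcription factor ATF3, 30.3 for IGFBP3, 27.2 for the receptor EPHA2, 23.5 for the matrix protein THBS1 and 20.2 for the ribosomal protein RPS27. LDHA, lactate dehydrogenase, had 685 tags and 3.72-fold (3.01–4.65). The chemokine CXCL8 had 17.9-fold (6.84–66.7), the inflammation regulator TNFAIP3 8.17-fold (3.61–22.8), CCN1 7.00-fold (4.98–10.1), HSPA9, a mitochondrial chaperone, 9.07-fold (3.74–28.6), P4HB 3.60-fold (2.60–5.11) and the nuclear RNA MALAT1 3.22-fold (2.44–4.30). FDXR, ferredoxin reductase, had at least 19.6-fold. In all, 13800 windows of 224 bases reached 2-fold, of which 1604 had an authors' p-value above 0.05 and 6971 passed the adjustment over 103423 putative peaks. Untreated cells thus had 2.18 times as many windows over IgG as listed, but fewer after the adjustment.

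The DFO pool exceeded the untreated pool at CDKN1A, MDM2 and GADD45A, each a known p53 target, while the fixed list of p53 targets and cell cycle genes did not pass its test (12 of 21, 57.1%, Fisher's exact test, adjusted p = 0.133). CDKN1A had 530 tags against 15, or 37.1-fold (22.3–66.7), MDM2 921 against 44, or 21.96-fold (16.2–30.4), and GADD45A 15.1-fold (11.1–21.0). PHLDA3 had 16.8-fold (8.27–39.7), NDRG1, a target of the hypoxia-inducible factors (HIF), 16.2-fold (8.55–34.4), the phosphatase PPM1D 13.8-fold (8.52–23.6), STX6 13.5-fold (6.88–30.3) and FDXR 12.6-fold (6.61–26.9). BTG2 had at least 34.7-fold and ATF3 at least 30.5-fold. TNFAIP3 had 8.13-fold (4.44–16.3), CXCL8 2.97-fold (2.12–4.22), HMOX1 3.15-fold (1.37–8.11), LDHA 2.02-fold (1.77–2.30), the ferritinophagy receptor NCOA4 2.45-fold (1.71–3.55) and MYH9 3.81-fold (2.47–6.07). HIF is known to be stabilised by DFO. Of 29 HIF targets and glycolytic genes with a peak in any annotated table, 26 (89.7%) had a window higher after DFO, against 33.6% of all 7300 genes with a peak (Fisher's exact test, two-sided, adjusted p = 7.8e-08). When peaks were assigned to the gene of the nearest promoter, the list had 16 of 24 (exact test, adjusted p = 0.0334). This call held under each alternative tried for the gene lists, and each of the other list calls was lost or turned under some alternative. Of 11 cytokine and inflammation genes, 9 had such a window (Fisher's exact test, adjusted p = 0.0107), a call that was lost with the nearest promoter (8 of 11, adjusted p = 0.0896). In all, 7384 windows reached 2-fold and 3166 still did when the tags of windows with 10000 or more normalised tags (pile-ups) were left out of both totals. Leaving them out multiplies each fold of the DFO pool over the untreated pool by 0.757, so listed folds near 2, such as that of LDHA, fall under the threshold. Of the 7384 windows, 724 (9.80%) overlapped a window listed as higher in untreated cells.

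Fewer ribosomal and respiratory chain genes than background had a window higher after DFO. Of 50 mitochondrial ribosomal protein genes, 2 (4.00%) had such a window (Fisher's exact test, adjusted p = 2.1e-05), and with the nearest promoter 5 of 55 (adjusted p = 0.00176). Of 51 cytosolic ribosomal protein genes, 5 did (exact test, adjusted p = 0.00195), and of 38 nuclear genes of respiratory complexes I, II, III and V, 3 did (adjusted p = 0.00408). These last calls were lost with the nearest promoter (exact test, adjusted p = 0.0853 for both lists). At a p-value of 1e-10 or lower, all 3 calls were lost (exact test, adjusted p = 0.563, 0.402 and 0.959). The cytosolic list then turned to 9.80% against 6.14% of background. With pile-up tags left out of the totals, all 3 calls were lost (exact test, adjusted p = 0.0542, 0.510 and 0.191). The lists then had 4.00%, 9.80% and 5.26%, still below a background that fell from 33.6% to 17.8%. Folds over IgG also rest on the pool totals, but they were not rescaled without pile-up tags. Against IgG, 13 of the 50 mitochondrial ribosomal protein genes had a DFO window (26.0%, against 51.1% of background), with an exact test's adjusted p = 0.00370, and 14 of 55 with the nearest promoter (adjusted p = 0.00419). That call was lost against genes at or above the median tag count (11 of 21, exact test, adjusted p = 0.0680) and at a p-value of 1e-10 or lower (adjusted p = 0.420). Of the cytosolic ribosomal protein genes, 22 of 51 did (43.1%, exact test, adjusted p = 0.565), which did not pass. Among random lists matched on tag count, however, that list stood at percentile 0. The respiratory complexes had 8 of 38 (exact test, adjusted p = 0.00276), a call lost with the nearest promoter (adjusted p = 0.0853). The members that did have a window higher after DFO included MRPL49 (2.79-fold, 1.80–4.43), RPS19 (3.58-fold, 2.56–5.09, in an intron), RPS27 (7.23-fold, 4.39–12.6), SDHA (2.59-fold, 1.67–4.10, in an intron) and UQCRC1 (2.47-fold, 1.43–4.39, in an intron).

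**Figure D1:**
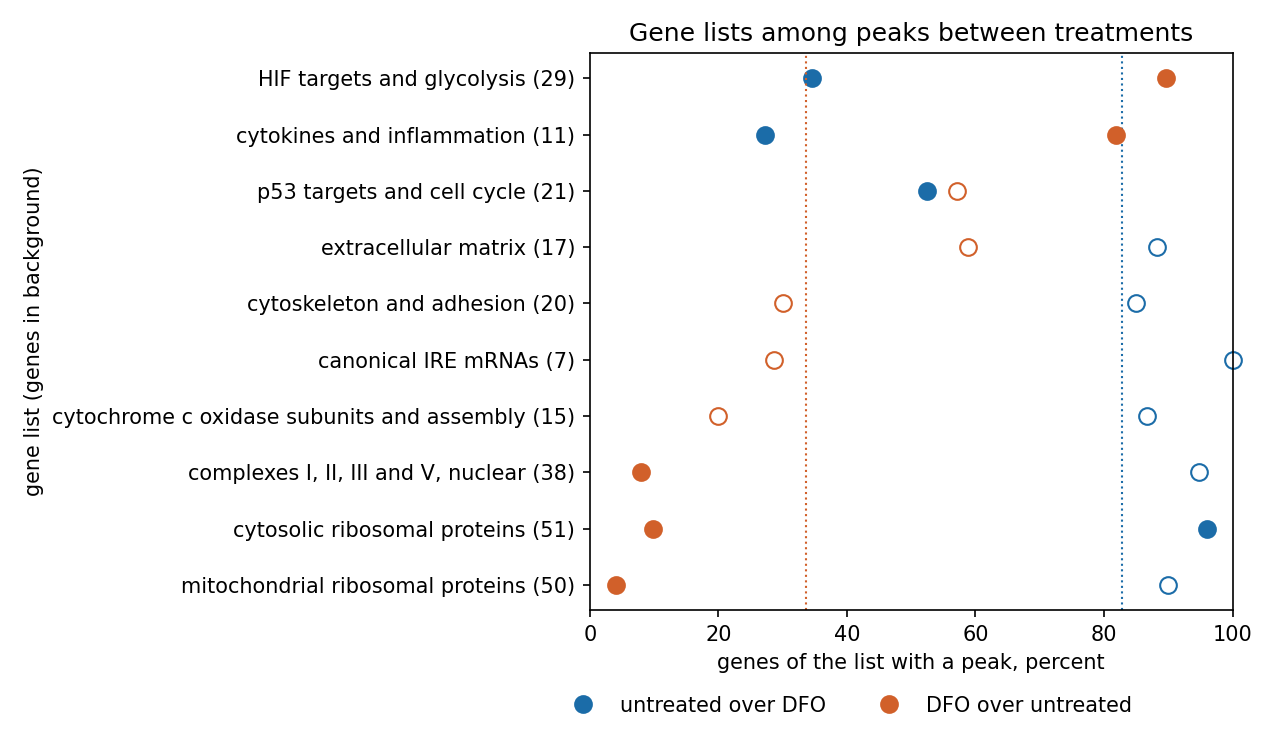
Share of each gene list with a window higher in untreated cells (blue) or after DFO (orange), in percent of the list's genes with a peak, whose number stands in brackets. Filled points passed the adjusted Fisher's exact test, open points did not, and dotted lines mark all 7300 genes with a peak: 26 of 29 HIF targets lie to the right of the DFO line and 2 of 50 mitochondrial ribosomal protein genes to its left.

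Over the DFO pool, the nucleolar protein NPM1 had in the untreated pool 264 tags against 13, or 19.4-fold (11.1–36.8), in an exon (NPM1 has pseudogenes too), ATP5F1E, an ATP synthase subunit, 11.8-fold (5.76–28.1), HSPA8 7.42-fold (5.55–10.1), the cyclin CCNB1 5.72-fold (3.08–11.6), TXNRD1 4.57-fold (2.80–7.82), EEF1G 4.01-fold (2.86–5.73), EEF1A1 3.41-fold (3.01–3.87), RPS6 3.32-fold (2.67–4.16) and VIM 2.70-fold (2.15–3.42). Among genes chosen by fold, the highest lay where tags are uncertain. MIR4485, inside a nuclear copy of mitochondrial ribosomal RNA, had 8841 tags against 5 and 1685-fold (722–5191), MTRNR2L10 109-fold (66.0–196), MTRNR2L1 89.0-fold (74.8–107) and MTRNR2L2 28.1-fold (25.9–30.6). MTRNR2L6 had at least 149-fold, MIR4461 at least 111-fold, the actin pseudogene ACTG1P20 at least 75.6-fold, SNORA66 at least 43.0-fold, RUBCNL at least 43.7-fold and PCBD2, in an intron by MIR4461, at least 34.5-fold. RPL31, a ribosomal protein gene with pseudogenes, had 44.1-fold (16.9–163). Cytokine genes had such windows less often than background, 3 of 11 against 82.7% (Fisher's exact test, adjusted p = 0.00120), also with the nearest promoter (3 of 11, adjusted p = 0.00344). HIF targets (10 of 29, exact test, adjusted p = 7.5e-07) and p53 and cell cycle genes (11 of 21, adjusted p = 0.00974) did too, but not with the nearest promoter (adjusted p = 0.0896 and 0.275). The p53 and cell cycle list passed in the opposite direction among windows with a p-value of 1e-10 or lower (28.6% against 10.4%, exact test, adjusted p = 0.0495) and at 8-fold or more (19.0% against 3.73%, adjusted p = 0.0474). The HIF list turned there too, without passing (13.8% and 10.3%, exact test, adjusted p = 0.752 and 0.341). Cytosolic ribosomal protein genes had them more often (49 of 51, exact test, adjusted p = 0.0464), a call lost with the nearest promoter (adjusted p = 0.0853). Every gene of the background has a peak in some table. A list's shares in the opposite directions therefore depend on each other and are not separate evidence. In all, 31932 windows reached 2-fold, 4.32 times as many as in the other direction, of which 57.9% had an annotation and 15138 passed the Benjamini-Hochberg adjustment over putative peaks. The untreated windows had 110 bases and a minimum of 7 tags, and those of the DFO pool 224 bases and 13 tags, so the lists were not called alike.

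The canonical IRE mRNAs were the reference for IRP2 binding. FTL, the ferritin light chain, had its window with the most tags over the 5' UTR in exon 1 of 4, at chr19 49468660–49468770. It held 317 tags against 27 of IgG in untreated cells, or 6.20-fold (4.18–9.56). After DFO the window at chr19 49468655–49468879 had 177 tags against 41, or 2.28-fold (1.61–3.28), and the untreated pool exceeded the DFO pool by 3.36-fold (2.65–4.29). FTL has pseudogenes, so its tags are uncertain. TFRC, the transferrin receptor, had its window with the most tags in the 3' UTR, in exon 19 of 19. It had 43 tags against 2 in untreated cells, or 11.4-fold (2.96–96.7), at chr3 195778555–195778665. After DFO it had 165 tags against 13, or 6.69-fold (3.81–12.8), at chr3 195778562–195778786, and exceeded the untreated pool by 2.71-fold (2.02–3.67). Another 3' UTR window of TFRC had 10.0-fold (4.96–23.6) over IgG after DFO and at least 8.54-fold in untreated cells. TFRC windows listed between the pools were mostly higher after DFO. Outside the 3' UTR these ran from 2.21-fold in exon 9 to 7.74-fold (3.68–18.8) in exon 7, and in the 3' UTR from 2.47-fold to 3.89-fold. The rise was thus not confined to the 3' UTR. TFRC windows higher in untreated cells held few tags against a DFO pool at the floor. They were at least 8.22-fold in exon 8 (26 tags), 6.64-fold in exon 12 (21 tags) and 2.85-fold in exon 14 (9 tags). The exon 12 window lay inside a larger window listed as higher after DFO (4.87-fold, 2.504–10.4), a place chosen after its values were seen. The larger window was credited with only 11 untreated tags, so these opposed calls were not counted alike. PFN2 had 5.60-fold (2.25–17.9) over IgG in untreated cells and 2.85-fold (1.43–6.27) after DFO, both in its 3' UTR. EPAS1, which encodes HIF-2α, had 3.61-fold (1.63–9.47) after DFO in its 3' UTR in exon 16 of 16, where it exceeded the untreated pool by 2.29-fold (1.36–3.98), and 2.92-fold (1.55–5.83) in another 3' UTR window. In untreated cells EPAS1 had 3.17-fold (0.705–29.1) and at least 3.16-fold over IgG in the 3' UTR, and 2.82-fold (0.806–15.1) in exon 11 of 16, where it was at least 5.06-fold higher than after DFO. No EPAS1 window lay in the 5' UTR. In untreated cells CDC42BPA had 3.17-fold (0.705–29.1) in exon 8 of 35 and SLC11A2 2.11-fold (0.421–20.4) in exon 15 of 17. Both intervals include no difference. After DFO CDC42BPA had at least 3.10-fold, in exon 28 of 35. These exon windows lie outside the UTRs. In untreated cells CDC42BPA also had windows in its 3' UTR, in exon 35 of 35. They had at least 3.16-fold (10 tags) and 2.11-fold (8 tags, 0.421–20.4) over IgG. FTH1, SLC40A1, ALAS2, CDC14A and HAO1 had no annotated window. A peak anywhere in the gene was counted, whether or not it lay at the IRE. Of the 7 IRE mRNAs with a peak, 5 were among the peaks of both treatments, against 31.6% of background (Fisher's exact test, adjusted p = 0.133), so the list did not pass. With peaks limited to an authors' p-value of 1e-10 or lower, 2 of them were, and the list passed (Fisher's exact test, adjusted p = 0.0179).

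**Figure D2:**
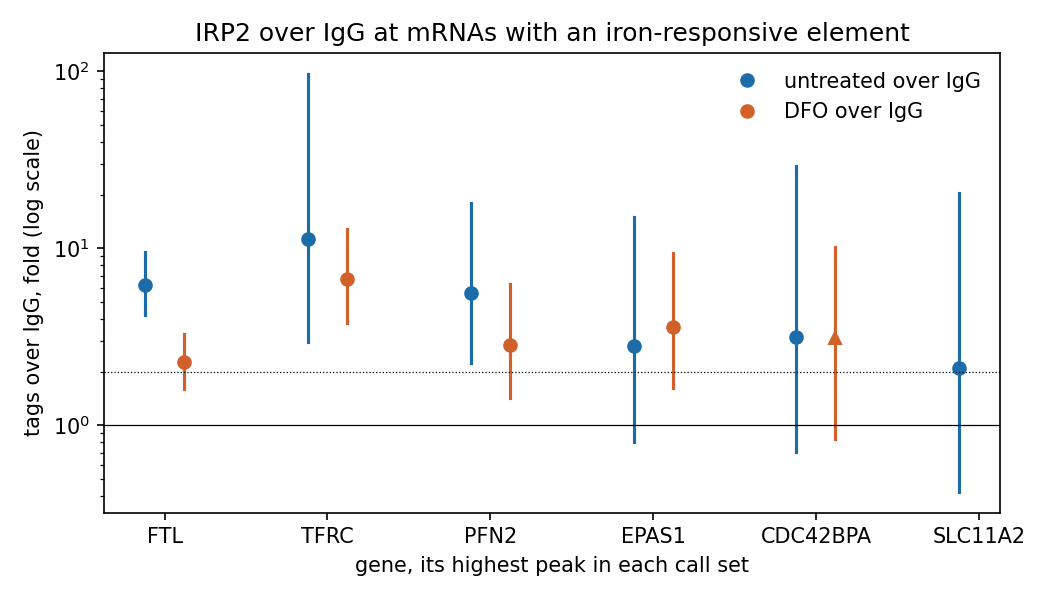
Fold of IRP2 over IgG (log axis) at the window with the most tags of the canonical IRE mRNAs named in the text in untreated cells (blue) and after DFO (orange), with 95% exact intervals for counting error. The triangle is a lower bound, the dotted line marks the authors' 2-fold threshold, and FTL has 6.20-fold in untreated cells and 2.28-fold after DFO. The 3' UTR window of FTL, not drawn, has 6.69-fold and 4.65-fold. Points of one gene can come from different places. For EPAS1 they lie in exon 11 in untreated cells and in the 3' UTR after DFO, and for CDC42BPA in exon 8 and exon 28.

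Cytochrome c oxidase, the terminal enzyme of the respiratory chain, is named in the title of the study. Of the 15 genes with a peak in the fixed list for its subunits and assembly, 13 had a window higher in untreated cells and 3 higher after DFO. Neither share passed its test against background (Fisher's exact test, adjusted p = 1 and 0.664). Over IgG in untreated cells, COX7A2 had 13.2-fold (3.47–112), COX8A 4.75-fold (2.47–10.2), LRPPRC 4.36-fold (1.55–16.9), COX5B 2.56-fold (1.12–6.86) and COX7C 2.09-fold (1.26–3.60), while COX7A2L had at least 7.91-fold and TACO1 at least 5.38-fold. After DFO, COX8A had 2.32-fold (1.52–3.67), LRPPRC 3.69-fold (1.56–10.6), CYCS 3.09-fold (2.06–4.79) in an intron, and COX17 at least 3.75-fold. The untreated pool exceeded the DFO pool by 4.63-fold (2.02–12.4) at COX5B, 3.90-fold (1.99–8.36) at COX4I1, 3.40-fold (1.85–6.67) at COX7A2 and 2.79-fold (1.78–4.49) at COX7C. The DFO pool exceeded the untreated pool at CYCS by 2.10-fold (1.60–2.77) and LRPPRC by 2.04-fold (1.15–3.76), both in introns. Neither gene encodes a subunit of the enzyme, and both folds fall under 2-fold when pile-up tags are left out of the totals. On the mitochondrial genome, 11 windows were higher over IgG in untreated cells and 5 after DFO. Between treatments, 7 were higher in untreated cells and 0 after DFO. Among the untreated windows, the most tags lay at positions 899–1009, in the ribosomal RNA region, with 37243 tags and 3.21-fold (3.13–3.30) over IgG and 3.05-fold (2.98–3.11) over the DFO pool. Among the DFO windows, they lay at positions 748–972, with 38854 tags and 3.82-fold (3.71–3.93) over IgG.

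The other fixed lists gave fewer calls. Extracellular matrix genes had peaks of both treatments more often than background (12 of 17 against 31.6%, Fisher's exact test, adjusted p = 0.00897), as did cytoskeleton and adhesion genes (13 of 20, adjusted p = 0.0179). Neither call held with the nearest promoter (exact test, adjusted p = 0.0896 and 0.275), and the cytoskeleton list stood only at percentile 67.5 of random lists matched on tag count. Small nuclear, nucleolar and other abundant noncoding RNAs were less often among peaks of untreated cells only (71 of 105, exact test, adjusted p = 0.00805) and of DFO only (21 of 105, adjusted p = 0.0464), and both calls were lost with the nearest promoter (adjusted p = 0.0896 and 0.937). Among windows with a p-value of 1e-10 or lower, these RNAs passed in the opposite direction, with 22.9% against 2.47% in untreated only (exact test, adjusted p = 7.6e-16) and 9.52% against 3.64% in DFO only (adjusted p = 0.0167). Lists without any call are given by their members with a window higher after DFO. These were 2 of 4 reported IRE candidates, with LRPAP1 at 2.91-fold (1.50–5.97), 5 of 12 genes of iron uptake, storage and export, and 7 of 20 genes of mitochondrial iron, heme and iron-sulfur clusters. They were also 2 of 20 translation factors, 2 of 21 oxidative stress genes, 4 of 18 chaperones and unfolded protein response genes, 4 of 23 RNA-binding proteins and 0 of 7 histones. Among random lists matched on tag count, translation factors, oxidative stress genes and RNA-binding proteins stood low, at percentiles 0.015, 0.08 and 0.1. The list of mitochondrial iron, heme and iron-sulfur clusters stood at percentile 85.7. Airway epithelial markers had 1 of 2 (KRT7, at least 3.10-fold), mesenchymal markers 0 of 4 and blood cell markers 0 of 1. In untreated cells over IgG, 51 of 51 cytosolic ribosomal protein genes had a window (exact test, adjusted p = 0.0322), a call that was lost with the nearest promoter (adjusted p = 0.210) and turned to 82.4% of the list with exon, UTR and end-of-transcript windows alone.

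Of the windows over IgG, 6127 in untreated cells (20.3%) overlapped a DFO window by at least 1 base, and 6040 DFO windows (43.8%) overlapped an untreated one. After merging, 6040 windows were shared, where draws of the same sizes matched on tag count gave 6835 (6752–6919). The draws hold only places called in some list, which raises the number expected. Of 7300 genes, 2949 had a peak over IgG in both treatments, and draws of genes could not test this, since every one of these genes has a peak over IgG in some treatment. The authors' annotated table of untreated cells held 17189 windows found both over IgG and over the DFO pool, and that of DFO held 5206 found over IgG and over the untreated pool. Their table of both treatments held 4514 windows, of which 1311 were also higher in untreated cells and 764 also higher after DFO, so peaks of both treatments are not peaks of equal height.

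Peaks lay in different parts of genes. Exons other than UTRs held 61.0% (60.3–61.8) of the peaks of untreated cells only, 37.7% (36.3–39.0) of those of DFO only and 45.0% (43.5–46.5) of those of both treatments. Introns held 9.29% (8.86–9.73), 24.8% (23.6–26.0) and 9.50% (8.66–10.4), 3' UTRs 18.4% (17.8–19.0), 25.9% (24.7–27.1) and 32.7% (31.3–34.1), and 5' UTRs 1.22% (1.06–1.39), 2.36% (1.97–2.81) and 1.60% (1.25–2.00), with exact binomial intervals. Between untreated only and DFO only, the adjusted p of Fisher's exact test over peaks was 3.1e-192 for exons, 7.0e-165 for introns, 2.9e-30 for 3' UTRs and 3.5e-08 for 5' UTRs. Peaks are not replicates, so these tests describe the pooled libraries. At a p-value of 1e-10 or lower, exons held 22.2% and 3' UTRs 49.4% of the peaks of both treatments. Introns then held 4.24% of the peaks of untreated only, 23.2% of those of DFO only and 4.44% of those of both treatments. The exon share was 43.9% in untreated only and 32.2% in DFO only, a smaller gap than among all peaks. In untreated only, 5' UTRs held 0.303%, transcript ends 12.7% and promoters 10.3%. The authors' IRE motif lay in 37.2% (36.5–38.0), 37.9% (36.6–39.2) and 49.5% (48.1–51.0) of the peaks, and the peaks of both treatments were wider, with a mean of 145 bases against 100.

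**Figure D3:**
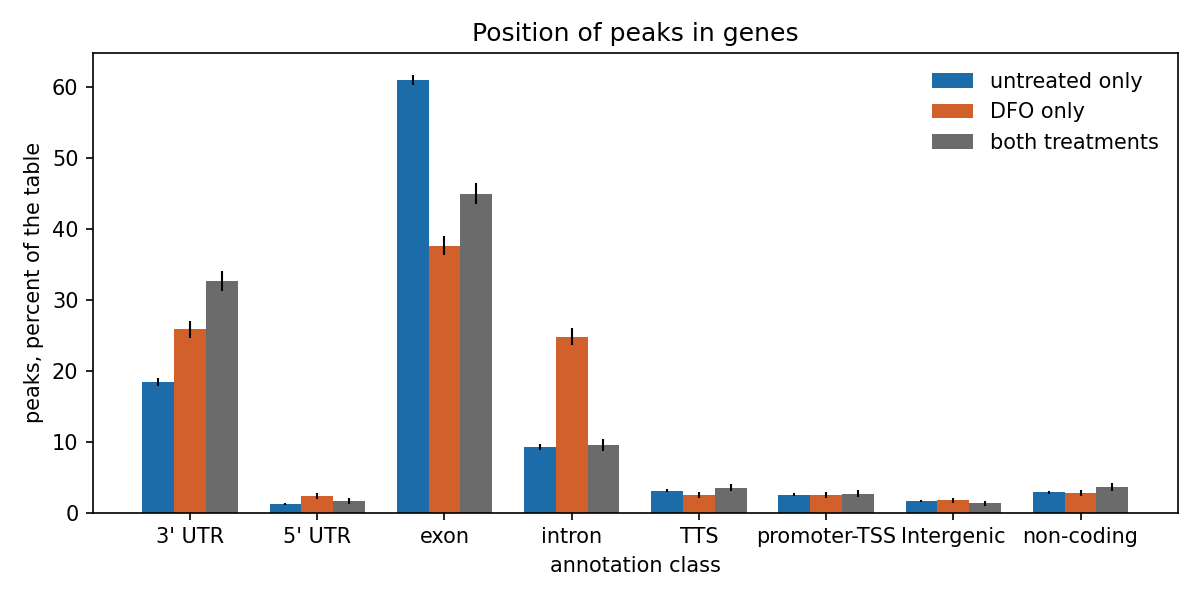
Percent of the annotated peaks in each annotation class for untreated only (blue), DFO only (orange) and both treatments (grey), with 95% exact binomial intervals. Introns hold 24.8% of the peaks of DFO only and 9.29% of those of untreated only.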

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

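The test of pile-ups was chosen after the result was seen, and the authors' motif was taken up after the data were examined, in place of a planned search.

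On the mitochondrial genome, the highest windows over IgG that had no entry in the annotated tables lay at positions 2714–2824 in untreated cells (21223 tags, 3.32-fold) and 2264–2488 after DFO (31703 tags, 4.5-fold), and they were singled out as signal above IgG in windows outside the annotated tables. No explanation was tested for them.

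More windows were higher in untreated cells than after DFO (31932 against 7384, a ratio of 4.32). With 1 tag minimum for both lists and neighbouring windows merged, the ratio was 1.66 (1.61–1.71), above the bound of 1.5 set for smaller windows and a lower minimum as the whole cause, though most of the excess went with them. Pile-up windows listed between the pools, as the cause, would need a larger share of the DFO pool, which lowers its scaled tags elsewhere. They held 30.6% of the untreated pool and 8.24% of the DFO pool, a ratio of 3.71. Of these windows, 28 were listed as higher in untreated cells and 1 after DFO, so a larger untreated share largely followed from the listing. The shares show only that the shift in scaling from these listed windows goes the other way. Pile-ups under 2-fold, which are not listed, and more binding in untreated cells stay open and untested, the latter since the pools have no replicates.

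HIF targets stood out among the windows higher after DFO, and p53 targets such as CDKN1A had high folds there, though their list did not pass. A candidate explanation is that the cells held more of these RNAs, carried into IgG and IRP2 alike. In shared peaks of 22 such genes, relative to other shared peaks, IRP2 tags rose 3.44-fold and IgG tags 1.79-fold with IgG at the floor counted as the floor, a ratio of 1.91 (1.23–3.34), or 1.44 (0.925–2.47) with it counted as 0. The bound was met under the first of these readings alone, so more RNA in the cell and more capture by IRP2 cannot be told apart here, because 34.0% of the 53 peaks lay at the IgG floor in untreated cells.

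The authors' motif lay in 49.5% of the peaks of both treatments and 37.2% of those of untreated cells only. Per 100 bases, the ratio of hits between these tables was 1.02 (0.983–1.07), in line with wider peaks holding more bases to search. Strand was read only for hits in exon and UTR peaks. In those of both treatments, 52.0% (49.96–54.0) lay on the transcript's strand, and the interval included 50%, the bound set for hits on either strand. The share was 55.9% (54.7–57.1) in peaks of untreated cells only and 53.03% (50.6–55.5) in those of DFO only, with intervals above 50%. The intervals of DFO only and both treatments overlap. No shuffled sequence was searched, so the share that chance gives was not measured. Selection of the motif by IRP2 was not tested.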

How the results depend on the processing

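The tests with adjustment over putative peaks, 1 tag minimum, totals without pile-ups, the nearest promoter, and opposite calls left out were chosen after the result was seen. No paired analysis was possible on the lists used here, because the authors pooled the replicates before calling peaks. Leave-one-out was not run for the same reason. The search for IRE structures in peaks and its alternatives were not run, since sequence of hg19 was not used here. The counting depth limits most windows: the compared library lay at the floor in 49.7% to 62.6% of each list.

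In the order untreated over IgG, DFO over IgG, untreated over DFO and DFO over untreated, windows numbered 786, 1184, 3295 and 1014 at a p-value of 1e-10 or lower, 398, 348, 794 and 125 at 8-fold or more, and 16053, 7056, 17969 and 3845 at or above the median tag count. Stricter thresholds keep fewer windows by construction. Adjustment over putative peaks left 5188, 6971 and 15138 in the first 3 lists. With 1 tag minimum, the untreated lists held 10888 and 12634. Without pile-up tags, 3166 windows stayed higher after DFO, a count that could only fall, since this scaling lowers every such fold. Over IgG, DFO then had more windows than untreated cells at 1e-10 and after adjustment. Shared windows numbered 0 with at least 50% of each window covered, since 110 of 224 bases cannot reach it, and 226 at 1e-10 in both. Counts without the mitochondrial genome, with strand ignored (which changes nothing in unstranded lists), or without opposite calls (31173 and 6660) stayed within 1.5 times.

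Of the 154 list tests, 54 passed at 1e-10 and 8 of the 27 calls held with the nearest promoter. IRE mRNAs passed at 1e-10 with 2 members in both treatments and 3 in untreated over IgG. The lists below turned to the other side of their background, and the cause was not tested. Those that also passed there were p53 and cell cycle genes at both thresholds, small nuclear and nucleolar RNAs in both tables, and HIF targets in untreated over IgG at 8-fold. At 1e-10 they were HIF targets (6.90% in untreated only, 13.8% in untreated over IgG and 13.8% in untreated over DFO), p53 and cell cycle genes (28.6% in untreated over DFO), cytosolic ribosomal proteins (3.92% in DFO only, 9.80% in DFO over untreated), cytokines (9.09% in untreated over IgG) and small nuclear and nucleolar RNAs (22.9% in untreated only, 9.52% in DFO only). At 8-fold they were complexes I, II, III and V (2.63% in DFO only and in DFO over IgG), HIF targets (3.45%, 13.8% and 10.3% in the same tables as above), p53 and cell cycle genes (19.0% in untreated over DFO), mitochondrial ribosomal proteins (2.00% in DFO only) and cytokines (9.09% in untreated over IgG). With exon, UTR and end-of-transcript windows alone, cytosolic ribosomal proteins in untreated over IgG had 82.4%. Of the 27 calls, 22 held there, 16 with the higher background, 7 at 1e-10, 5 at 8-fold and 19 without pile-up tags. The scaling without pile-up tags was applied only to folds between the pools.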

Other observations

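The stem-loop search in UTRs took the place of a planned search after the data were examined and before its result was seen, and the other tests were planned.

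Iron genes had windows higher in either treatment, at shares for which no test against background passed. Their list of uptake, storage, export and regulation shares TFRC, FTL and SLC11A2 with that of the IRE mRNAs. Of 12 genes of iron uptake, storage, export and regulation with a peak, 8 had a window over IgG after DFO and 12 in untreated cells, and 11 (91.7%, against 82.7% of background) had a window higher in untreated cells. A window higher after DFO was found in 5 (41.7%, against 33.6%), among them NCOA4, the receptor for ferritin degradation, and HMOX1, heme oxygenase. Of 20 genes of mitochondrial iron, heme and iron-sulfur clusters, 7 had a window higher after DFO and 18 a window higher in untreated cells. FDXR, which serves iron-sulfur cluster synthesis and is also a known p53 target, had 12.6-fold (6.61–26.9). None of these lists passed its exact test.

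Extracellular matrix genes had a window over IgG after DFO in 14 of 17 (82.4%, against 51.1% of background), which missed the adjusted threshold (Fisher's exact test, adjusted p = 0.0684). Of these genes, 10 of 17 had a window higher after DFO (exact test, adjusted p = 0.135) and 15 of 17 a window higher in untreated cells.

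An IRE-like stem-loop in a UTR was tested as a hypothesis for peaks in both treatments. Of 6789 genes with a UTR searched, 257 had such a stem-loop. Of these, 85 had a peak in both treatments, where 98.2 were expected from random genes matched on UTR length and tag count (10000 draws), and the stratified odds ratio was 0.726 (0.534–0.985), with a permutation p = 0.983, one-sided. The bound set against the hypothesis was met, for stem-loops as matched by this search. How many of the 257 genes were matched by chance was not measured, so the result does not speak to IREs that IRP2 binds. The search found the stem-loop in 4 of 7 canonical IRE genes with a peak, so it misses known elements, and it covered UTRs of another genome build by gene name.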
